A study of Mus musculus with 6 samples.

How the data were processed

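RNA was extracted with TRIzol from cultured mouse ES cells, and libraries were made with the TruSeq Stranded mRNA kit and sequenced in pairs on an Illumina HiSeq instrument, per the labels' protocols. The 6 libraries fall into 2 genotypes of 3, Tex19.1+/- and Tex19.1-/-, by the genotype given in the labels. The submitters' processing notes name Trim Galore 0.4.1, TopHat2 2.1.0, HTSeq 0.11.2 and edgeR, and the build mm10. The version of edgeR, the annotation, the strand setting of the counting, the filter on low counts and the form of the test are not given in the sources used here.

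The values analysed are the authors' own comparison of the genotypes in 1 table with a row per gene symbol. Per the file headers, the authors deposited a log2 fold change, a mean expression as log2 CPM (read counts scaled to library size), a p-value and a false discovery rate for each of 10128 genes. The lowest mean in the deposited log2 CPM column was 1.82, so genes of lower expression had been removed by the authors. The CPM values of the table sum to 85.1% of the total that CPM values of all genes would reach. The authors' adjusted p-values equal Benjamini-Hochberg values recomputed here within 6.7e-05, and their size implies 10129 tests. For 8 genes the deposited p-value is listed as 0. The direction of the log2 fold change is not named per the file headers; it was read as Tex19.1-/- over Tex19.1+/-, because Tex19.1 has the lowest value.

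A count model with genotype as its term had been planned before the data were examined. Values per library were not used here, so that model, the values of single libraries, their depth, the spread between them and the part of the naming rule that asks every library of one genotype to lie beyond every library of the other could not be applied. The authors' log2 fold changes and adjusted p-values stand in their place, with a threshold of 0.05, and no standard deviation is given. Precision is set by the authors' p-values alone. The targeted gene and its paralog Tex19.2 were to be named in any case; Tex19.2 was not analysed here. Beyond it, the genes named are the 12 largest rises and 12 largest falls past the threshold with a mean of at least 5 CPM, and up to 4 members with the smallest p-value from each of 25 gene lists fixed before the data were examined. Any other gene is named as chosen after its values were seen. Some genes that this rule would name are not reported here.

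The lists cover pluripotency states, lineages, fibroblasts and feeder cells, germline and 2-cell-like genes, cohesin, the N-end rule pathway, the proteasome, retrotransposon silencing, imprinting, p53, interferon, metabolism, stress, the cell cycle, genes next to Tex19.1, Y-linked genes and Hox genes. Of 798 listed genes 527 were measured, and 24 lists had at least 3 measured members. Each list was tested with camera in its version for precomputed statistics (limma 3.58.1, R 4.3.3), two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. The statistic was the normal z of the authors' p-value with the sign of the fold change, limited to 38 in size. Member counts use the adjusted p over all genes and, beside it, one adjusted over the list alone. Camera asks whether a list differs from the other genes.

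Gene positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names: 9573 symbols matched a GENCODE gene and 137 matched through older symbols, which leaves 418 genes without a position. Shifted stretches were sought on chromosomes 1 to 19 and X by recursive splitting of the fold changes in gene order, limited to 1 in size, against 200 shuffles of gene order. A stretch is called shifted where it holds at least 10 genes and its median differs from that of all genes by at least 0.2. Chromosome medians have 95% intervals from 2000 bootstrap draws over genes, which describe the spread of genes and not of libraries.

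As a check, the z values were shuffled over the 10128 genes, which removes any correlation between genes. Of 400 random lists without a planted change, 2.75% then passed an unadjusted p of 0.05. This rate does not speak for lists of genes that vary together. In the same shuffled values, 50 planted lists of 20 genes were called higher in 42.0% of cases at a log2 shift of 0.1, 94.0% at 0.25 and 100% at 0.5. Of 100 stretches of 30 genes planted in fold changes shuffled over 9690 genes, 12.0% were found at a shift of 0.2 and 100% at 0.4 and 0.6. The shift of 0.2 equals the least shift that the rule accepts, so the rate of 12.0% is partly set by the rule. At 0.2, 1 stretch was called elsewhere, and 0 at the larger shifts.

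The alternatives were an adjusted p under 0.01, Bonferroni adjustment, genes of at least 16 CPM, leaving out the shifted stretches and the Y chromosome, p-values from the spread of 301 genes of like expression (1.4826 times the median absolute deviation), fold changes with a lowess trend on GC content and transcript length removed (span 0.3) and p recomputed from the standard error that the authors' p implies, and camera on ranks, on fold changes or with a correlation of 0.05. For p-values from genes of like expression, the median of the 301 genes was first subtracted, so higher and lower are there relative to that median. GC content and length were known for 95.9% of genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.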

Results

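Gene expression was measured by RNA sequencing in mouse embryonic stem (ES) cells that carried 1 working copy of Tex19.1 or none. The cells derive from E14Tg2a, a male ES line of 129/Ola background grown in serum with leukaemia inhibitory factor. There were 3 libraries of Tex19.1+/- cells and 3 of Tex19.1-/- cells. Tex19.1 is a mammal-specific gene of germ cells, placenta and pluripotent cells, whose protein binds the ubiquitin ligase UBR2 and whose loss derepresses some retrotransposons in mice. The comparison asks which transcripts differ between ES cells with and without it. All values below come from the authors' deposited table of 10128 genes, which gives 1 log2 fold change per gene and no value per library, so the depth of each library is unknown and no spread can be printed beside a fold change. Positive log2 fold changes are read as higher in Tex19.1-/- cells.

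Tex19.1 itself, on chromosome 11 from 121146143 to 121148319 (GRCm38, plus strand, ENSMUSG00000039329.8), had the lowest log2 fold change in the authors' deposited table, -6.92, which leaves 0.828% of the heterozygous level. Its p-value and adjusted p are listed as 0 there, and its mean over the libraries was 13.8 CPM. The header does not name the direction, and the direction was taken from this gene, so Tex19.1 is no independent check of the labels. Of the 14 measured genes that flank it, 5 rose, 3 fell and 6 did not pass, counts that were the same when adjusted over the list alone. The smallest p-values among them in the authors' deposited table belonged to Slc16a3, a lactate transporter, at 0.32, Rfng at -0.28, B3gntl1 at 0.26 and Dcxr at -0.22.

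Among genes of at least 5 CPM, the largest falls apart from Tex19.1 included genes of the endoderm list and of the Y chromosome, and the largest rise was in the imprinted gene Mest. Mest, on chromosome 6 from 30723547 to 30748465, was 30.02-fold higher in Tex19.1-/- cells, a log2 fold change of 4.91 in the authors' deposited table. The next rises there were the potassium channel gene Kcnj3 and Arl14epl, both at 2.25, followed by the hedgehog-binding protein gene Hhip at 1.53, the membrane glycoprotein gene Prom1 at 1.48 and the thyrotropin-releasing hormone gene Trh at 1.43. Gadd45g at 1.29, Msantd4 at 1.28, the actin-binding calponin gene Cnn2 at 1.26, the semaphorin receptor gene Nrp2 at 1.20, Vwa5a at 1.17 and the POU factor gene Pou3f1 at 1.16 complete the 12 largest rises in the authors' deposited table among genes of at least 5 CPM. The 12 largest falls in the authors' deposited table among genes of that level were Tex19.1 itself, then the endocytic receptor gene Cubn at -2.93, the proteoglycan gene Srgn at -2.89, the Y-linked genes Uty at -2.83, Eif2s3y at -2.64 and Ddx3y at -2.37, and the growth factor receptor gene Pdgfra at -2.34. They end with Gata6 at -2.32, the collagen IV gene Col4a2 at -2.23, Nkx6-3 at -2.19, the membrane repair gene Dysf at -2.15 and Gata4 at -2.08, per the authors' deposited table. Each of these 24 changes had an adjusted p of 1.15e-29 or less in the authors' deposited table, the highest being that of Pou3f1.

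At an adjusted p under 0.05 in the authors' deposited table, 5236 of the 10128 genes changed, 2551 of them higher and 2685 lower in Tex19.1-/- cells. Most of these changes were small: their median size was 0.22 on the log2 scale, and 2279 of them were under 0.2. Changes of at least 2-fold were found for 148 genes, 37 higher and 111 lower. Of these, 114 had a mean of at least 5 CPM, 28 higher and 86 lower. The 9 genes under 4 CPM all had an absolute log2 fold change of at least 1.56 in the authors' deposited table, so a gene of that level stands in the table only with a large change. Each gene was also set against the median and spread of fold changes among genes of like expression, in place of the authors' test. In this way 629 genes passed, 191 higher and 438 lower than that median. For lists whose test passed, the members that pass in this way are given as the count against genes of like expression.

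**Figure D1:**
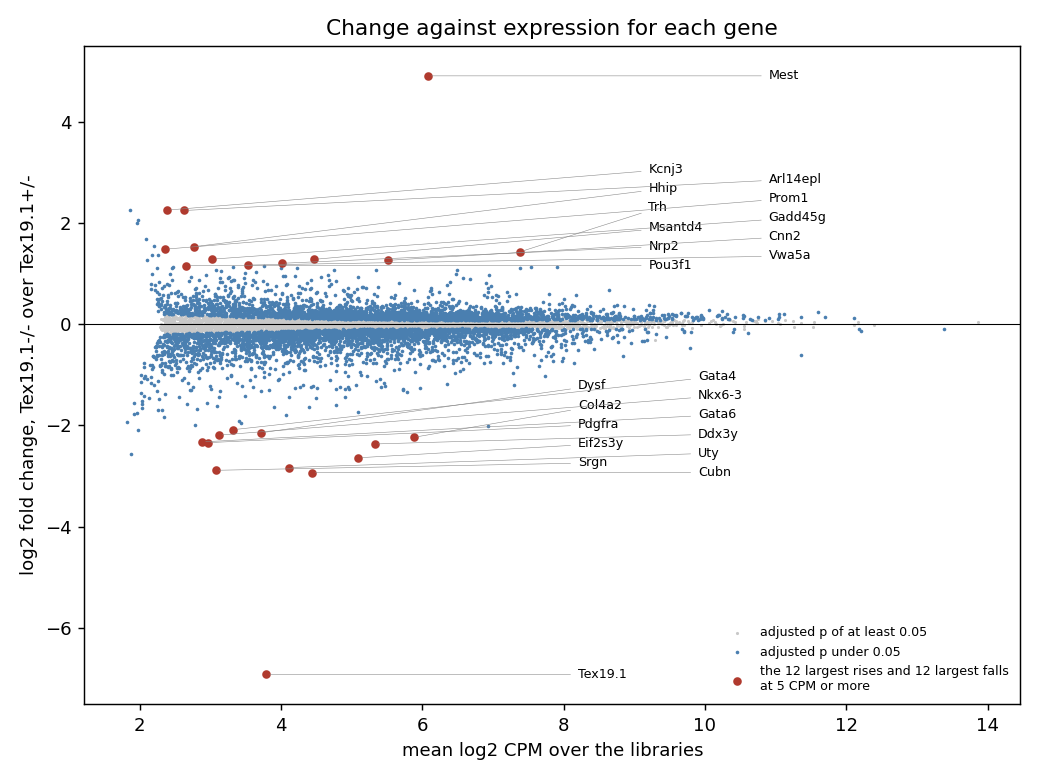
Log2 fold change (vertical axis, Tex19.1-/- over Tex19.1+/-) against mean log2 CPM (horizontal axis) for each of the 10128 genes of the authors' deposited table. Blue points have an adjusted p under 0.05 and grey points do not; red points are the 12 largest rises and the 12 largest falls among genes of at least 5 CPM, with Mest at 4.91 and Tex19.1 at -6.92.

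Genes of primitive and definitive endoderm were lower as a group. Of 17 measured members 15 fell, 10 of them at least 2-fold, and none rose, with the same counts when adjusted over the list alone. The median log2 fold change of the list was -1.56 (camera adjusted p = 1.82e-57), and 14 members fell against genes of like expression. The smallest p-values in the authors' deposited table belonged to Cubn at -2.93, the 2 adjoining basement membrane collagen genes Col4a1 at -2.01 and Col4a2 at -2.23, and Srgn at -2.89. The transcription factor genes Gata6 and Gata4, which drive endoderm formation, stood at -2.32 and -2.08 in the authors' deposited table. The members that did not pass, chosen after their values were seen, were Lrp2 at -0.08 and the keratin gene Krt18 at -0.01 in the authors' deposited table.

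Genes of the formative and primed epiblast, the states that follow naive pluripotency in the embryo, were higher as a group. Of 13 measured members 10 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 3.98e-07), and 7 rose against genes of like expression. Otx2, a homeobox gene of the early epiblast, was at 1.12, the cadherin gene Cdh2 at 1.04, Sox4 at 0.73 and Zic2 at 0.58 in the authors' deposited table. Naive and core pluripotency genes went both ways: 11 of 28 rose and 12 fell (12 and 13 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.713). In the authors' deposited table Fbxo15 stood at 0.46 and Zfp42, also known as Rex1, at 0.36, against -0.71 for Klf5 and -0.40 for the DNA demethylase gene Tet2. Klf5 lies on the stretch of chromosome 14 described below, where most genes were lower. Of the core factor genes, chosen after their values were seen, Pou5f1 was at -0.09 (adjusted p = 0.0534), Esrrb at -0.02 (adjusted p = 0.642), Nanog at 0.10 (adjusted p = 0.0359) and Sox2 at 0.23 (adjusted p = 5.86e-09) in the authors' deposited table. With a trend on GC content and length subtracted, Pou5f1 passed the threshold and Nanog did not.

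Of the other lineages, neuroectoderm genes were higher as a list, with 6 of 9 members up and 3 down (the same adjusted over the list alone), a median of 0.31 and a camera adjusted p of 0.00478; 3 rose against genes of like expression. That call was lost when ranks were tested (adjusted p = 0.138; range over 5 alternative settings 0.00748 to 0.138). Pax6 and Neurod1, transcription factor genes of neural development, were both at 0.87, Sox21 at 0.75 and the neuronal tubulin gene Tubb3 at 0.42 in the authors' deposited table. Among 6 trophoblast genes 3 rose and 3 fell (camera adjusted p = 0.373), with the placental cadherin gene Cdh3 at 0.93, Tfap2c at 0.86, Tead4 at -0.78 and Peg10 at -0.62 in the authors' deposited table. Mesoderm and primitive streak genes were split as well, 2 up and 2 down of 5 (camera adjusted p = 0.448), the TGF-beta family genes Lefty1 at 0.58 and Lefty2 at 0.38 against Bmp4 at -0.74 and Nodal at -0.29 in the authors' deposited table. Genes of fibroblasts and feeder cells showed no shift as a list (camera adjusted p = 0.713): 4 of 9 rose and 2 fell, from 0.42 for Cyr61 and 0.23 for Fn1 to -0.33 for Vim and -0.76 for Fbn1 in the authors' deposited table. The trophoblast, mesoderm and fibroblast counts were the same adjusted over the list alone. No Hox gene was among the genes measured.

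**Figure D2:**
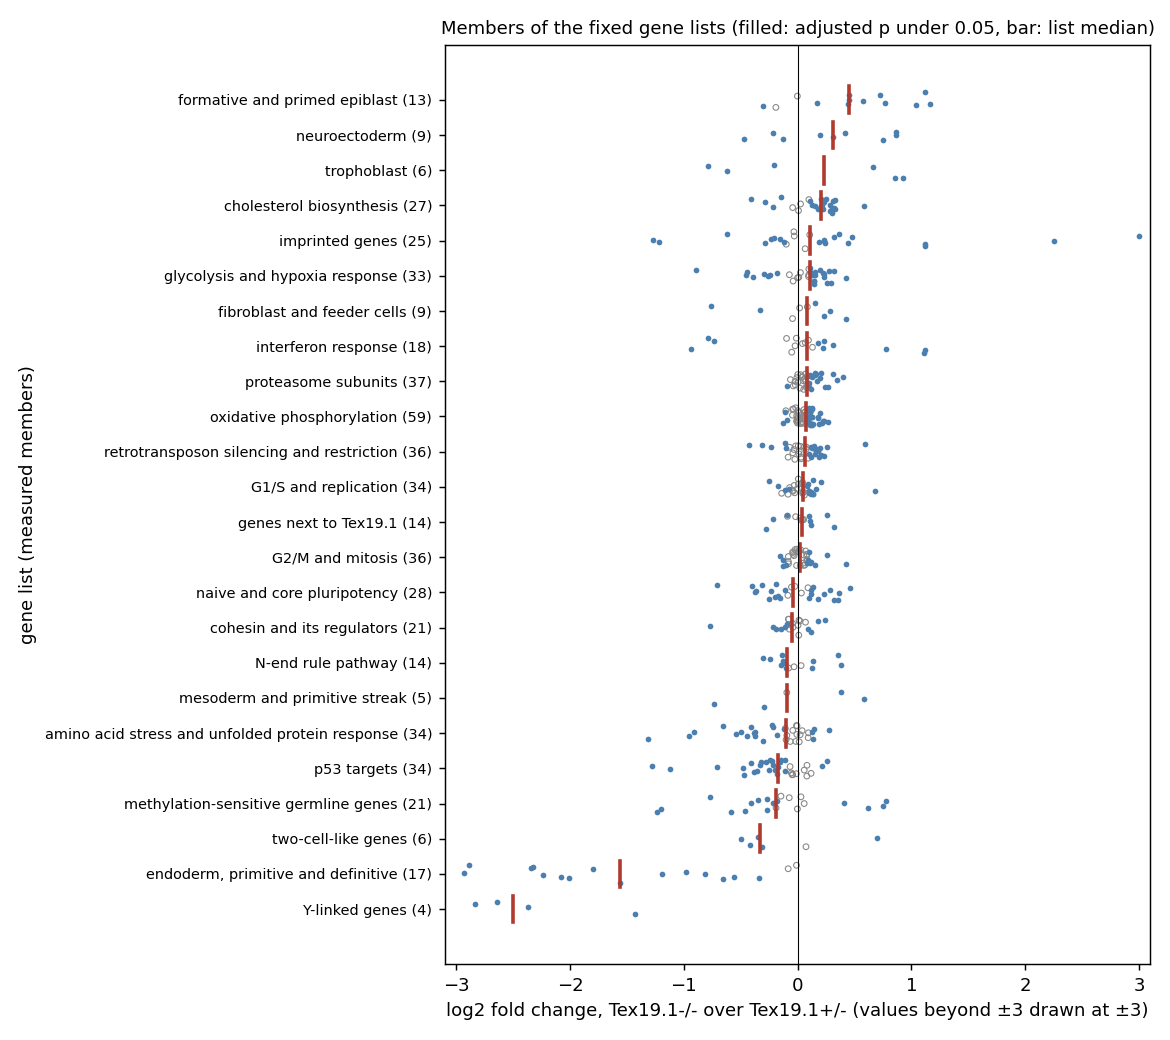
Log2 fold change (horizontal axis, values beyond 3 drawn at 3) of each measured member of 24 gene lists (vertical axis, number of measured members in brackets), from the authors' deposited table. Filled points have an adjusted p under 0.05 and red bars are list medians, which run from -2.50 for Y-linked genes and -1.56 for endoderm to 0.45 for the formative and primed epiblast.

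Germline genes that DNA methylation keeps silent in somatic cells were mostly lower. Of 21 measured, 11 fell, 2 of them at least 2-fold, and 4 rose (13 and 4 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.0466); against genes of like expression 4 fell and 2 rose. In the authors' deposited table the piRNA pathway gene Piwil2 was at -1.23, the meiotic genes Hormad1 and Stag3 at -1.20 and -0.77, and Tdrd12 at 0.75. Piwil2 lies on the chromosome 14 stretch; the list's call was lost without the shifted stretches and the Y chromosome (adjusted p = 0.175; range over 5 alternative settings 0.000249 to 0.179, with 1 of them past the threshold). Of 6 genes that mark cells resembling the 2-cell embryo, 4 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.685). Ddit4l at -0.50, Zscan4c at -0.41, Zfp809 at -0.31 and Calcoco2 at 0.69 had the smallest p-values of that list in the authors' deposited table; Zscan4c has near-identical copies among which reads may have been split. Genes that silence or restrict retrotransposons were not shifted as a list (camera adjusted p = 0.126): 15 of 36 rose and 5 fell (16 and 6 adjusted over the list alone). The small RNA processing genes Dicer1 and Drosha were at 0.59 and 0.26, the H3K9 methyltransferase gene Ehmt2 at -0.42 and Zfp809, which represses proviruses, at -0.31 in the authors' deposited table. Transcripts of retrotransposons themselves were not analysed here.

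Of 3 lists tied to the Tex19.1 protein, the N-end rule and cohesin lists were not shifted and the proteasome list was slightly higher. In the N-end rule pathway, which degrades proteins according to their first residue, 7 of 14 members fell and 4 rose (8 and 4 adjusted over the list alone; camera adjusted p = 0.760). The authors' deposited table gives Ubr2 at -0.30, Ubr4 at -0.24, the ubiquitin-conjugating enzyme gene Ube2a at 0.35 and Wdyhv1 at 0.39. Cohesin and its regulators hold sister chromatids together; 6 of 21 fell and 4 rose, counts that were the same adjusted over the list alone (camera adjusted p = 0.591). Apart from the meiotic subunit gene Stag3 at -0.77, those with the smallest p-values in the authors' deposited table stayed within 0.2 of 0: Esco1 at -0.19, Stag1 at 0.18 and Nipbl at -0.15. Smc3, the cohesin subunit gene, was chosen after its value was seen and stood at -0.08 (adjusted p = 0.0611) in the authors' deposited table; it passed with the trend on GC content and length subtracted. Proteasome subunits were slightly higher, with 18 of 37 up and 1 down (the same adjusted over the list alone) and a median of 0.08 (camera adjusted p = 0.0112); 0 of the 37 passed against genes of like expression. Psme2 at 0.39, Psmc5 at 0.34, Psme4 at 0.31 and Psme3 at 0.27 led that list in the authors' deposited table. Of the 18 that rose, 7 lie on chromosome 11, whose genes had a median of 0.07. Psmc5, Psme4 and Psme3 are among these 7. The proteasome call held in 3 of 5 alternative settings, with adjusted p from 0.000959 to 0.129.

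Imprinted genes, which are expressed from 1 parental allele, held some of the largest changes. Of 25 measured, 12 rose and 8 fell (13 and 9 adjusted over the list alone), 4 and 2 of them at least 2-fold, with a median of 0.11 (camera adjusted p = 0.00478); against genes of like expression 5 rose and 3 fell. Beside Mest at 4.91, the translational regulator gene Impact stood at 1.12, the cell cycle inhibitor gene Cdkn1c at -1.27 and H13, which encodes a signal peptide peptidase, at -1.21 in the authors' deposited table. H13 spans 152669461 to 152708670 on chromosome 2 and contains the gene Mcts2, chosen after its value was seen, which stood at 1.12 in the authors' deposited table. The 2 genes lie on the same strand, so reads from where they overlap cannot be told apart by strand. The list's call held in 3 of 5 alternative settings, with adjusted p from 3.72e-06 to 0.192.

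Targets of the tumour suppressor p53 were lower. Of 34 measured, 22 fell and 2 rose (the same adjusted over the list alone), with a median of -0.18 (camera adjusted p = 2.3e-05); 5 fell against genes of like expression. The apoptosis gene Pmaip1 was at -1.28, the death receptor gene Tnfrsf10b at -1.12, Perp at -0.71 and Plk2 at -0.47 in the authors' deposited table; Tnfrsf10b lies on the chromosome 14 stretch. Genes of amino acid stress and the unfolded protein response were lower too, 16 of 34 down and 4 up (the same adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0147); 7 fell against genes of like expression. The amino acid transporter gene Slc7a1 was at -0.96, the transcription factor genes Atf3 and Atf4 at -1.32 and -0.50, and the mitochondrial enzyme gene Shmt2 at -0.41 in the authors' deposited table. That call held in 3 of 5 alternative settings, with adjusted p from 0.00719 to 0.131. Interferon response genes were not shifted as a list (camera adjusted p = 0.115): 7 of 18 rose and 3 fell, the same adjusted over the list alone. In the authors' deposited table Ifitm1 was at 1.12, Oas1a at 1.11, Irf1 at 0.78 and Bst2 at -0.73; Ifitm1 and Oas1a belong to families of close paralogs. With only genes of at least 16 CPM the list passed (adjusted p = 0.0152; range over 5 alternative settings 0.0152 to 0.262).

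Cholesterol biosynthesis genes were higher: 19 of 27 rose and 4 fell (the same adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00705); 1 rose against genes of like expression. Insig1, which restrains sterol synthesis, was at 0.58 and the desaturase gene Scd2 at -0.29 in the authors' deposited table. The call held in 4 of 5 alternative settings, with adjusted p from 0.000959 to 0.077. Subunits of oxidative phosphorylation were slightly higher, 22 of 59 up and 3 down (21 and 3 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0409); 0 of the 59 passed against genes of like expression. The ATP synthase genes Atp5g2 at 0.26, Atp5k at 0.24, Atp5c1 at 0.22 and Atp5g1 at 0.21 led it in the authors' deposited table. With the trend on GC content and length subtracted, Atp5g2 stood at 0.18, Atp5k at 0.16, Atp5c1 at 0.19 and Atp5g1 at 0.22. The call held in 2 of 5 alternative settings, with adjusted p from 0.0029 to 0.262. No list was tested with that trend subtracted. Glycolysis and hypoxia genes showed no shift as a list (camera adjusted p = 0.375): 17 of 33 rose and 8 fell (19 and 8 adjusted over the list alone). Pfkfb3, an activator of glycolysis, was at 0.43 and the glycolytic enzyme gene Gpi1 at 0.29, against -0.89 for the collagen hydroxylase gene P4ha2 and -0.44 for Bnip3l, which lies on the chromosome 14 stretch, in the authors' deposited table.

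Cell cycle genes were not shifted as lists. Of 34 genes of G1/S and replication 13 rose and 4 fell (the same adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.209), and of 36 genes of G2/M and mitosis 8 rose and 4 fell (7 and 4 adjusted over the list alone), with a median of 0.02 (camera adjusted p = 0.355). The replication clamp gene Pcna was at 0.68 and the phosphatase gene Cdc25b at 0.43 in the authors' deposited table; both lie on a shifted stretch of chromosome 2. The other members named by p-value were Rrm2 at -0.25, Rfc4 at 0.20 and Ccne1 at -0.17 for G1/S, and Kif20a at 0.26, Kif23 at -0.16 and Bub1 at 0.15 for G2/M, in the authors' deposited table.

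The Y-linked list was lower. All 4 members of the Y-linked list fell at least 2-fold, with the same count adjusted over the list alone and against genes of like expression (camera adjusted p = 6.92e-35). The call held in 4 of 4 alternative settings, with adjusted p from 3.8e-48 to 0.00271. Camera treats these neighbours on the Y chromosome as nearly independent, so its p-value is too small if they shift together. Whether loss of Tex19.1 played a part was not tested, since genotype and cell population cannot be separated here. In the authors' deposited table Uty was at -2.83, Eif2s3y at -2.64, Ddx3y at -2.37 and Uba1y at -1.43, which leaves 14.05%, 16.1%, 19.4% and 37.1% of the heterozygous level. The list's members lie between 818649 and 1286629 on the Y chromosome. Far from them and not in the list, Gm47283, from 90784738 to 90816464, does not bear on that part. It stood at -0.09 (adjusted p = 0.0776) in the authors' deposited table. It was chosen after its value was seen, as were the X-linked counterparts of the list's members, which were nearer to 0 in the authors' deposited table: Ddx3x was at 0.13 (adjusted p = 0.00263), Kdm6a at 0.01, Eif2s3x at -0.01 and Uba1 at -0.02.

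Along the other chromosomes, the median log2 fold change of genes, from the authors' deposited table, lay between -0.03 on chromosome 9 and 0.02 on chromosome 19, with 3 exceptions. Chromosome 11 had a median of 0.07 (95% bootstrap interval over its 807 genes 0.06 to 0.08), the X chromosome 0.07 (0.05 to 0.09, 315 genes) and chromosome 14 -0.12 (-0.17 to -0.06, 363 genes). The shift of chromosome 14 came from its distal part. From Ptk2b at 66153257 to Tm9sf2 at 122159604, 103 of 107 genes had values below 0, with a median of -0.67 and quartiles of -0.77 and -0.52, and 100 fell. The 250 genes before this stretch had a median of 0.00. The 6 genes beyond it had a median of -0.37, and 4 of them fell and 2 rose. Chromosome 2 held 2 short stretches shifted upward: 20 of 20 genes from 130590002 to 132587729 had values above 0, with a median of 0.53, and so had 10 of 10 genes from 144599897 to 148692949, with a median of 0.55. These stretches were located after the values were seen, by a search over all chromosomes. They and the Y chromosome hold 142 genes, Gm47283 included, 17 of which changed at least 2-fold, 16 lower and 1 higher. The endoderm genes Gata4 and Sox7 lie on chromosome 14 before the stretch, from 63198922 and 63943673.

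**Figure D3:**
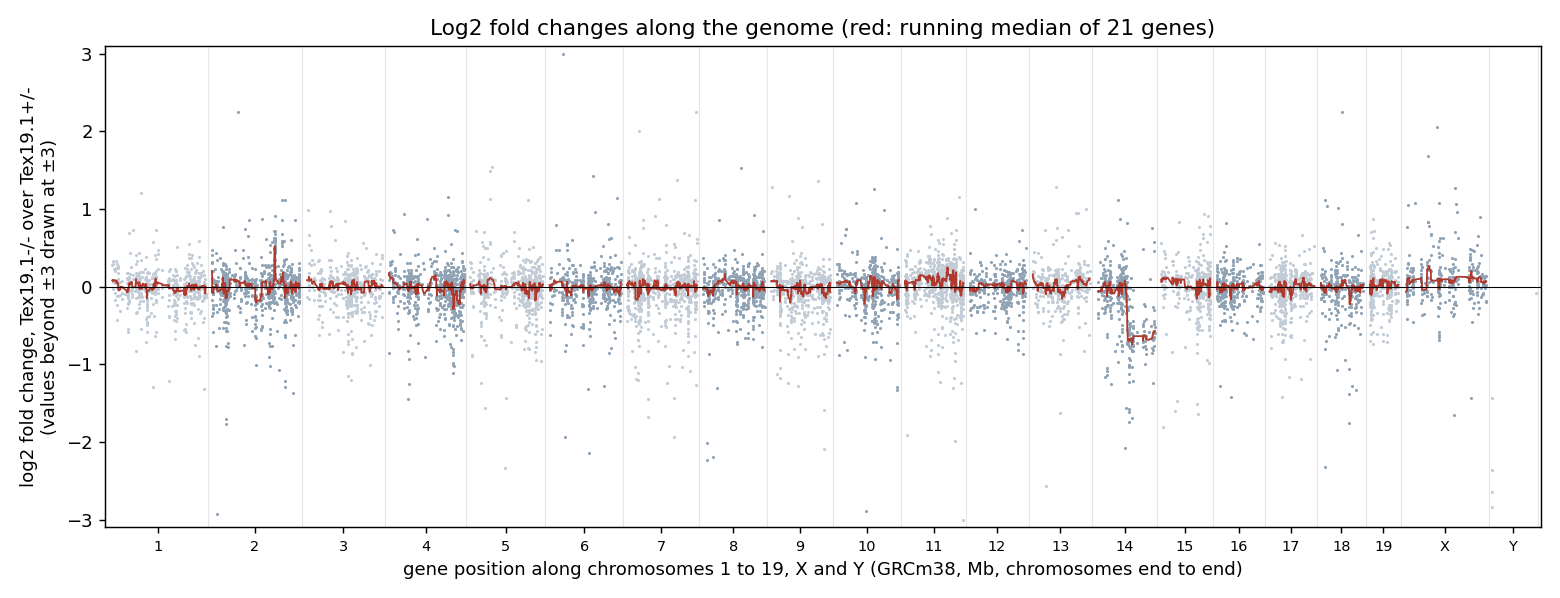
Log2 fold change of each gene (vertical axis, Tex19.1-/- over Tex19.1+/-, values beyond 3 drawn at 3) against its position along the chromosomes (horizontal axis, GRCm38), from the authors' deposited table. The red line is the running median of 21 neighbouring genes; it steps down to about -0.67 over the distal part of chromosome 14 and up over a short stretch of chromosome 2.

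All p-values for single genes are the authors', and the labels do not say whether the 3 libraries of a genotype came from separate cultures or clones, so they measure only the spread between these libraries, which may be technical. Camera was run with a preset correlation of 0.01, because an estimated one needs values per library; with 0.05 in its place and nothing else changed, the calls for endoderm, formative and primed epiblast, Y-linked, neuroectoderm and p53 target genes held, and those for the germline, proteasome, imprinted, cholesterol, oxidative phosphorylation and amino acid stress lists were lost. With 0.05 and a second choice changed, p53 targets were also lost on fold changes (adjusted p = 0.0922) and neuroectoderm without the shifted stretches (0.0987) and on ranks (0.260).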

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

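All alternatives reported here were chosen after seeing the data. The planned ones (other scalings, tests and count filters, estimated correlation, fry, a replicate block and leaving out each library) were not run, since each needs values per library. No paired analysis was possible because the table holds no value per library. Nor could other splits of the libraries be counted. Depth is unknown, so its limits cannot be given. At Bonferroni, which passes fewer genes by construction, 2413 genes passed, 970 higher and 1443 lower. With p from genes of like expression, a different test, the counts were 629, 191 and 438. Among genes of at least 16 CPM, 54 changed at least 2-fold, 13 higher and 41 lower, against 148 at the main setting. Fewer genes enter, but the count of all changed genes fell by less, from 5236 to 3825. The 2-fold changes thus lay more among genes under 16 CPM. All other counts stayed within 1.5 times the reported ones. Of 136 genes past the threshold among those chosen for naming, 135 kept their direction and their side, Tex19.1 included, when the GC and length trend was subtracted, Nanog being the exception; with p from genes of like expression 88 did, and 48 kept the direction but no longer passed. Of 10 such genes not past it, Pou5f1, Smc3 and Gm47283 passed and Lrp2 changed sign with the trend subtracted, and Kdm6a and Krt18 changed sign against genes of like expression. The 22 chromosome medians stayed within their intervals under both alternatives. On ranks the neuroectoderm (adjusted p = 0.138), germline (0.0795) and imprinted (0.192) lists no longer passed; on fold changes the germline (0.105), proteasome (0.0767) and oxidative phosphorylation (0.121) lists. With a correlation of 0.05 the germline (0.179), proteasome (0.129), imprinted (0.0551), cholesterol (0.0770), oxidative phosphorylation (0.262) and amino acid stress (0.131) lists were lost. At 16 CPM oxidative phosphorylation (0.0594) and amino acid stress (0.0594) were lost and the interferon list passed (0.0152). Without the shifted stretches and the Y chromosome the germline list was lost (0.175). For losses not named as built in, the cause was not tested. The endoderm, formative epiblast and p53 lists passed under all 5 settings and the Y-linked list under the 4 that measure it.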

Other observations

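Genes first named in this part were chosen after their values were seen, as were the tests of copy number and of parental class.

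Several genes not named above stood far from 0. The meiosis gene Stra8 was at -1.94, and the testis genes Fmr1nb at 2.06 and Usp26 at 1.69, the last 2 at means of 3.95 and 4.25 CPM, in the authors' deposited table. Foxq1 at -2.57, Pth1r at -2.09, the X inactivation RNA Xist at -1.65 and the maternally expressed RNA H19, a member of the imprinted list, at 2.25 had means of 3.68, 3.94, 4.09 and 3.63 CPM in the authors' deposited table. Genes under 4 CPM stand in the authors' deposited table only with absolute log2 fold changes of at least 1.56. A further 89 genes had means of 4 to 5 CPM, among them Xist, Usp26, Slit2 (4.61), Oas1a (4.72) and Atf3 (4.74). Of all 10128 genes 148 changed at least 2-fold, and 114 of these were among the 10030 genes of at least 5 CPM. The rest are more than the 9 genes under 4 CPM can hold, so large changes were also overrepresented at 4 to 5 CPM. The form of the filter is not given, so its part in this was not tested. The lactate dehydrogenase gene Ldhb, of 185 CPM, was at 1.14 in the authors' deposited table. On chromosome 5, 12 of 13 genes from 43662346 to 50059006 had values above 0, with a median of 0.19. The search over these same values set the bounds of this stretch, and it missed the shift of 0.2 needed to be called shifted. In the authors' deposited table this stretch includes Prom1 at 1.48, Slit2 at 1.54 and Fgfbp1 at 1.13.

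Neighbouring genes on chromosomes 14 and 2 shifted together. On chromosome 14 the authors' deposited table has abundant genes such as Tpt1 at -0.61, Xpo7 at -0.67 and Ipo5 at -0.47, and the tumour suppressor gene Rb1 at -0.79; Sox21 at 0.75 and Klf12 at 0.49 went the other way. For the strongest run, chance clustering is argued against, since 0 of 200 shuffles of gene order gave one as strong. For the chromosome 14 stretch, so is GC content or transcript length, since it kept a median of -0.67 after that trend was subtracted. The chromosome 2 stretches were not examined for GC content, length or expression level, so copy number was not tested for them. Their medians of 0.53 and 0.55 lie below the 0.58 of 3 copies against 2. A difference in DNA copy number between the cells of the 2 genotypes may account for the chromosome 14 stretch. The medians of its low, middle and high expression groups were -0.67, -0.72 and -0.59, a range of 0.13. Its median of -0.67 lies between the -0.58 of 2 copies against 3 and the -1 of 1 copy against 2. That 96.3% of its genes lay below 0 is no separate support, since the search picked the stretch for its low values. Which genotype would carry the change, and whether loss of Tex19.1 played a part, was not tested, since genotype and cell population cannot be separated here.

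None of the 17 measured endoderm genes, with a median of -1.56, lies on one of those stretches. A smaller share of endoderm-like cells in the Tex19.1-/- cultures is a candidate explanation that stays open. In a second list of endoderm genes, none of them in the first, 19 of 42 were measured, 14 fell and 3 rose, and the median was -0.37, between the bounds set for and against it. In the authors' deposited table the collagen chaperone gene Serpinh1 stood at -1.43, Htra1 at -1.09 and Flrt3 at -1.07, but Gpc3 at 0.79 and Kitl at 0.99, and the abundant Apoe at -0.02; other cells in the cultures may express these too. Whether loss of Tex19.1 itself lowered these genes was not tested, since genotype coincides with the cultures.

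Of the table's genes 51.7% passed the threshold, and the coefficient of variation implied by the authors' p-values was 0.0322 (median over 448 genes with a log2 CPM of at least 8). It was 0.04 at a log2 CPM of 4.5 to 5.5 and 0.07 under 3. Without values per library, whether so small a spread reflects repeats of the same culture cannot be told.

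The imprinted genes went both ways, which raised the hypothesis that paternally expressed genes rose and maternally expressed genes fell. Of the paternally expressed members that changed 7 rose and 4 fell, and of the maternally expressed 4 rose and 3 fell, so that no such split was detectable (two-sided Fisher's exact test, p = 1.0), with 18 genes too few to exclude one.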
